A study of Mus musculus with 12 samples.

How the data were processed

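The series holds RNA sequencing of kidney tissue from C57BL/6 mice, 12 libraries in 3 groups of 4, grouped by the treatment label of each library. Per the labels' protocols, about 60 mg of frozen tissue was ground and total RNA was extracted with Trizol. HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 are named in the submitters' processing notes without their roles. The genome build, annotation, library kit and strandedness are not given in the sources used here, so no coordinates are printed. Genes are identified by the symbols and NCBI gene numbers in the deposited table.

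The deposited table has 19036 genes with unique symbols. It gives FPKM for all 12 libraries in columns named after them, made by the authors and rounded to 2 decimals, and the authors' group mean FPKM equal the means of those columns. The authors also deposited estimated counts per gene, of which 34.3% are not whole; per the file headers, 10 of these columns name a library. A block of 14 per-sample columns was not used: 2 have no heading, and 12 stand under a heading that is displaced against its neighbours. Of these, 12 share a fixed column total and 2 hold counts, so that cisplatin libraries 1 and 2 had no count column here. Estimated count totals were 15.76, 16.05, 16.08 and 16.52 M in vehicle libraries 1 to 4, 17.74 and 18.15 M in cisplatin libraries 3 and 4, and 18.03, 18.17, 17.86 and 17.47 M in combination libraries 1 to 4. The authors' group means of the estimated count total were 16.1, 17.8 and 17.88 M. Kap alone took 11.01 to 12.29% of the FPKM in vehicle libraries, and Gpx3 4.57 to 5.95% in the other 8.

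Values were tested as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (linear model with 3 group means over all 12 libraries, 9 residual degrees of freedom, moderated with a mean trend). Genes with an FPKM of at least 1 in at least 4 libraries entered, 12428 in all. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within a comparison. Fold changes are on the log2(FPKM + 1) scale and understate changes of genes with low values. Errors beside log2 fold changes are standard errors, and those beside FPKM are SD. The labels call the libraries biological replicates and give 4 mice per group; p-values measure the spread between these libraries. No FPKM columns were identical among the 12 libraries. Chi-square per degree of freedom of the counts was at least 4.53 between libraries of the same group with a named count column; cisplatin libraries 1 and 2 were not in that check.

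The samples, tests, alternatives, 37 gene lists and the rule for named genes were fixed before the data were examined. The lists cover pathways, cell types of the kidney and transcripts of other tissues; 30 with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, and with an estimated correlation as an alternative. Of the listed symbols, 17 had no match in the table, including all 13 genes of the mitochondrial genome, whose list was not analysed here. List means per library were compared with exact two-sided permutation tests of 4 against 4 libraries, with 70 arrangements and a smallest p of 0.0286, adjusted over all lists and the 3 comparisons. The named genes of a comparison were an anchor set, the 6 highest and 6 lowest fold changes among passing genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM (predicted genes left out), and, per described list, the 3 passing members with the largest moderated statistic plus the most abundant member that did not pass. For reversal, the 6 genes with the largest cisplatin effect each way among those moved back were named. Scnn1g, Kcne1, Cldn19, Serpina1a, Apoc3 and the genes of the observations at the end were named after their values were seen. Some genes that the rule names are not reported here; they stay in the counts of genes and lists but not in the search for single libraries that stand apart. The segment marker lists were also chosen after the results were seen. The interval of the injury list mean came from the linear model of the list means of all 12 libraries.

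The design named edgeR's quasi-likelihood test as the main test if counts were present. Counts could be assigned for only 10 libraries, so FPKM of all 12 were kept as the main values, and edgeR 4.0.16 on the rounded estimated counts (14831 genes) was run as an added alternative, with DESeq2 1.42.0 on the same counts and limma on the FPKM of the same 10 libraries. Alternative analyses used a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, rescaling to TPM, the replicate number as a block, array weights, fits of only the groups compared, a minimum log2 fold change of 1, and leaving out each library.

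The limma, camera and edgeR steps were tested on simulated data with 200 changed genes. For cisplatin against vehicle, limma on 12428 genes recovered 84% of genes changed 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 4% of its calls false. For the combination against cisplatin the shares were 90%, 94% and 100%, with 4% false, and for the combination against vehicle 86%, 94% and 100%, with 5.9% false. At the smallest simulated fold, below 1.5, limma recovered 56%, 54% and 38% in the 3 comparisons, so that changes of that size were often missed. On 14831 genes, edgeR recovered 58%, 46% and 70% of genes changed 1.5-fold, 86%, 78% and 86% at 2-fold and 94%, 98% and 96% at 4-fold, in the same order, with 9.4%, 5% and 4.8% of its calls false. Camera recovered 3 of 3 raised lists in each comparison and called none of the others. The simulated genes varied independently of each other, so this does not show how camera behaves on lists of correlated genes.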

Results

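Kidney RNA of C57BL/6 mice, a common inbred laboratory strain, was sequenced 72 h after injection of vehicle or cisplatin. Cisplatin is a platinum chemotherapy drug that injures the renal tubule, and it was given at 25 mg/kg. The 12 libraries, labelled as biological replicates, fell into 3 groups of 4: vehicle, cisplatin, and cisplatin with the compound 84-B10 at 15 mg/kg, called the combination group here. Pretreatment with 84-B10 lasted 48 h before cisplatin. The labels differ on whether the cisplatin group also received this pretreatment, and each library was placed in the group its treatment label names. Estimated counts totalled 15.76 to 16.52 M in the vehicle libraries, 17.47 to 18.17 M in the combination libraries, and 17.74 and 18.15 M in cisplatin libraries 3 and 4. Totals of cisplatin libraries 1 and 2 were not used here. The comparisons ask what cisplatin did to the kidney transcriptome and, following the series title, whether 84-B10 moved it back towards the vehicle state. No library of mice given 84-B10 without cisplatin was analysed here.

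Cisplatin raised the measured genes of the tubular injury and inflammation lists and most p53 targets. It lowered most listed genes of the proximal tubule and of the loop and distal tubule, and the listed enzymes of the citric acid cycle. Havcr1 (NCBI gene 171283), which encodes an injury molecule of proximal tubule cells, stood at 0.533 ± 0.407 FPKM in vehicle kidneys and at 625 ± 92.1 FPKM after cisplatin (mean ± SD, n = 4 per group). Lcn2 (NCBI gene 16819), the gene of the injury marker neutrophil gelatinase-associated lipocalin, stood at 0.688 ± 0.608 against 1368 ± 394 FPKM. Egf (NCBI gene 13645), made in the thick ascending limb and distal tubule, fell from 302.4 ± 34.8 to 5.66 ± 1.81 FPKM. Slc34a1 (NCBI gene 20505), the main phosphate transporter of the proximal tubule, fell from 4462 ± 84.7 to 643 ± 279 FPKM.

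Of 12428 genes tested, 9710 changed between cisplatin and vehicle, and 2096 of these changed at least 2-fold, 1494 upward and 602 downward. The libraries of the 2 groups did not overlap for 8902 genes, 71.6% of those tested, where chance alone gives 2.86%. The largest rises under the naming rule were those of Lcn2 (log2 fold change 9.67, SE 0.29, adjusted p = 3.93e-12), Havcr1 (8.70), Sprr1a (8.53), Krt20 (8.21), Cdkn1a (7.42) and Fgg (6.88). Sprr1a encodes a cornified envelope protein, Krt20 a keratin, Cdkn1a the cell cycle inhibitor p21 and Fgg the fibrinogen gamma chain. The largest falls were those of Inmt, an indolethylamine methyltransferase (-6.74, SE 0.10, adjusted p = 8.4e-15), Egf (-5.54), the amino acid transporter Slc7a13 (-5.28), Nat8f6 (-5.20), Nat8f7 (-5.14) and Slc22a28 (-4.87). Nat8f6, Nat8f7 and Slc22a28 belong to families of close paralogs whose reads can be shared, so their single values are uncertain.

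All 30 measured genes of the tubular injury list rose, with a median log2 fold change of 3.86, among them Anxa3 (4.17). Camera gave an adjusted p of 7.24e-11 for the list and an adjusted p = 0.134 with an estimated correlation. Of 35 p53 targets 33 rose and 2 did not pass, with a median of 2.02 (camera adjusted p = 5.27e-10; adjusted p = 0.0653 with an estimated correlation). Phlda3 (5.35) and Gtse1 (3.59) rose, as did Mdm2, the ubiquitin ligase that restrains p53 (2.60). Xpc, a DNA damage sensor, stood at 12.1 ± 0.506 against 12.1 ± 0.600 FPKM (adjusted p = 0.918), with a log2 fold change that turned to -0.27 with median-of-ratios scaling. All 27 measured inflammatory genes rose, with a median of 2.299 (camera adjusted p = 4.05e-08; adjusted p = 0.105 with an estimated correlation). Among them were the cytokine gene Lif (3.51), the signalling suppressor Socs3 (3.59) and the adhesion molecule gene Icam1 (3.11), and the chemokine gene Ccl2 rose by 2.14. Of 12 macrophage markers 10 rose, among them Cd68 (4.45), Cd14 (2.91) and Itgam (1.31), while the macrophage receptor gene Csf1r did not pass (-0.03, adjusted p = 0.792). Camera gave the list an adjusted p of 0.0322, and an adjusted p = 0.362 with an estimated correlation. The same numbers of genes passed when p was adjusted over the list alone in the injury, p53 and inflammation lists. Of the macrophage markers, 10 rose and 1 fell when adjusted over the list alone.

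Of 50 proximal tubule genes 44 fell and 4 rose, with a median log2 fold change of -1.45 (camera adjusted p = 4.75e-18; adjusted p = 0.222 with an estimated correlation). Cyp4b1, a cytochrome P450, fell by 3.05, and Kap, the androgen-responsive gene with the highest vehicle level, fell by 2.68 (SE 0.15). The organic anion transporter Slc22a6 (-2.44), the organic cation transporter Slc22a2 (-1.33) and the endocytic receptor Lrp2 (-2.14) also fell. The glucose transporter gene Slc5a1 did not pass (-0.31, adjusted p = 0.116). In the loop and distal tubule 20 of 24 genes fell and none rose, with a median of -1.43 (camera adjusted p = 4.48e-11; adjusted p = 0.134 with an estimated correlation). Pvalb, a calcium-binding protein of the distal convoluted tubule (-3.75), the transcription factor Emx1 (-1.57) and Umod, which encodes uromodulin (-1.72), fell. Adjusted over the list alone, the counts in both lists were the same. Of 22 collecting duct genes 12 fell and 6 rose, with a median of -0.26 and the same counts adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.222 with an estimated correlation). The water channel gene Aqp2 was among those that rose (1.12).

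The 22 citric acid cycle genes all fell, with a median of -0.63 (camera adjusted p = 1.01e-13; adjusted p = 0.134 with an estimated correlation). Among them were Pcx (-1.47), Idh2 (-1.34) and Sucla2 (-0.89). Fatty acid oxidation genes moved in both directions: 15 of 27 fell and 6 rose, with a median of -0.28 (camera adjusted p = 4.57e-05; adjusted p = 0.264 with an estimated correlation). Acsm3, a medium-chain acyl-CoA synthetase, fell by 2.501, Acads by 0.99, Acad10 by 1.07 and Acadm by 0.85, and Ech1 did not pass (-0.04). Of 24 Nrf2 targets, the antioxidant response genes, 19 rose and 3 fell, with a median of 0.85 (camera adjusted p = 0.0112; adjusted p = 0.222 with an estimated correlation). Akr1b8 (5.03), Srxn1 (2.95), Hmox1 (2.36), Txnrd1 (1.89) and Nqo1 (1.74) rose. Of 27 cell death genes 19 rose and 3 fell, with a median of 0.95 (camera adjusted p = 0.0161; adjusted p = 0.317 with an estimated correlation). They included Birc3 (2.42), Tnfrsf1a (1.92) and Bax (1.82). The necroptosis effector gene Mlkl rose by 2.09. The same counts were found with p adjusted over the list alone in these 4 lists.

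The lists of ferroptosis, an iron-dependent form of cell death, did not pass camera after cisplatin. Of 21 genes that promote it 8 rose and 4 fell (camera adjusted p = 0.901), and of 23 that restrain it 9 rose and 7 fell (camera adjusted p = 0.48); the counts adjusted over the list alone were the same. The means of both lists were higher after cisplatin, by 0.484 and 0.406 (exact two-sided permutation test, adjusted p = 0.0463 for each). Neither passed with per-gene z-scores (adjusted p = 0.0572 and 0.156), where no list mean passed in any comparison and 0.0572 is the value of the smallest exact p. The restraining list did not pass with median-of-ratios scaling (adjusted p = 0.0869). Both lists had a positive median (0.09 and 0.10) and a camera direction downward relative to other genes, and both medians were negative with median-of-ratios scaling (-0.19 and -0.17). Among members that passed, Acsl4 (1.98), Alox5 (2.61) and the zinc and iron transporter gene Slc39a14 (1.62) rose in the promoting list, and Gch1 (2.07), Mboat1 (1.33) and Nfe2l2 (1.33) rose in the restraining list. Gpx4, the lipid peroxide reductase, stood at 993 ± 106 FPKM after cisplatin against 902 ± 59.4 FPKM in vehicle kidneys and did not pass (adjusted p = 0.151). Lonp1, a mitochondrial protease gene, fell by 0.19 (SE 0.04), Sod2 by 0.80 and Ppargc1a by 0.62.

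The balance of rises and falls depended on library scaling. With the deposited FPKM 6999 genes rose and 2711 fell, whereas median-of-ratios scaling, which shifted the groups against each other by 0.295 on the log2 scale, gave 4618 and 4602, quantile normalization 4288 and 4783, and edgeR on the estimated counts of 10 libraries 5095 and 4754.

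**Figure D1:**
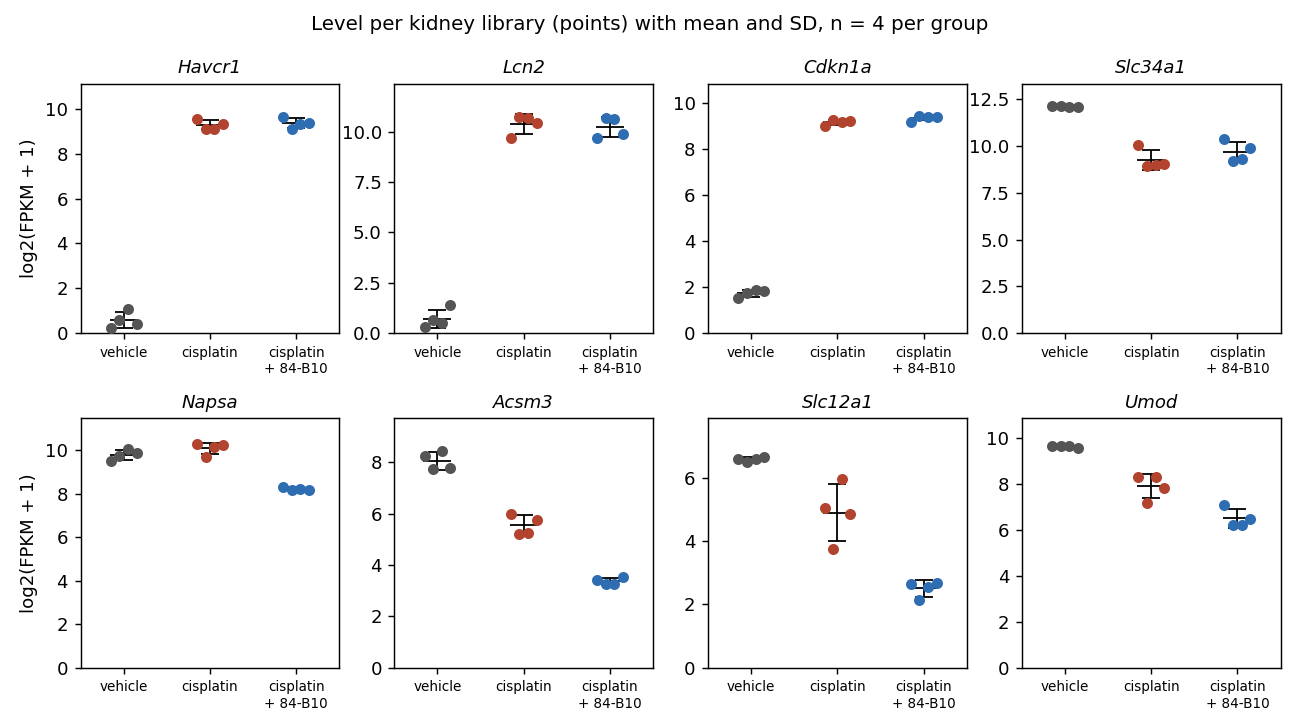
Level of 8 genes in each kidney library, as log2(FPKM + 1) on the vertical axis, for the vehicle, cisplatin and combination groups; points are the 4 libraries of a group, and bars give the mean and SD. Havcr1, Lcn2 and Cdkn1a were at similar levels in both cisplatin-treated groups (Havcr1 at 625 ± 92.1 FPKM after cisplatin and 667 ± 107 FPKM in the combination group), whereas Napsa, Acsm3, Slc12a1 and Umod were lower in the combination group.

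In the combination group the cisplatin response was mostly left in place, and a limited set of genes differed, most of them lower. Havcr1 (667 ± 107 against 625 ± 92.1 FPKM, adjusted p = 0.839), Lcn2 (1239.9 ± 415 against 1368 ± 394 FPKM, adjusted p = 0.846) and Cdkn1a (647 ± 43.4 against 570.1 ± 45.5 FPKM, adjusted p = 0.326) did not pass between the combination and cisplatin groups. Genes of the proximal tubule and the thick ascending limb were among those that fell. Napsa, an aspartic protease gene (NCBI gene 16541), fell from 1099.8 ± 187 to 299 ± 13 FPKM, and its vehicle libraries, at 891 ± 140.4 FPKM, overlapped the cisplatin libraries. Some genes that cisplatin had already lowered fell further. Acsm3 (NCBI gene 20216) fell from 47.4 ± 13 to 9.33 ± 0.949 FPKM. Slc12a1 (NCBI gene 20495), the sodium-potassium-chloride transporter, fell from 33.3 ± 20.1 to 4.75 ± 0.939 FPKM, and Umod from 248 ± 82.3 to 91.6 ± 29.1 FPKM (n = 4 per group).

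Between the combination and cisplatin groups 275 of 12428 genes changed, 54 upward and 221 downward, and all 69 that changed at least 2-fold fell. Rescaling to TPM gave 29 upward and 221 downward, and quantile normalization 76 and 249. The groups did not overlap for 1024 genes (8.2%, against 2.86% by chance), and 262 genes met both criteria. The largest falls under the naming rule were those of Akr1c18, a steroid dehydrogenase (-3.38, SE 0.42, adjusted p = 0.000511), Ceacam2 (-2.90), Serpina1d (-2.87), Cyp7b1, an oxysterol hydroxylase (-2.77), Methig1 (-2.60) and Serpina1f (-2.58). Akr1c18, Serpina1d and Serpina1f have close paralogs, so that reads may have been divided between family members. Each of the genes named for the largest falls also varied among vehicle libraries, with library 1 lowest and library 3 highest. Akr1c18 ranged there from 0.06 to 5.1 FPKM, Cyp7b1 from 6.25 to 35.21 and Serpina1d from 16.71 to 89.73. The cause was not tested. Rises were smaller: Mustn1 (0.74, SE 0.07, adjusted p = 3.25e-05), Spink8 (0.46), Rtl8b (0.45), Foxi1 (0.44), Mdk (0.44) and Pgam2 (0.42). The calls of Mdk, Rtl8b and Spink8 were lost without 8, 7 and 5 of the 12 libraries in turn. Of 6 measured transcripts typical of liver and muscle, Serpina1a (-2.31), another Serpina1 gene, and Apoc3 (-1.13) fell and the other 4 did not pass. The mean of that list was lower by 0.714 on the log2 scale (exact two-sided permutation test p = 0.0286, adjusted p = 0.0463). This p is the smallest that 4 against 4 libraries allow. The list mean did not pass with per-gene z-scores (adjusted p = 0.197). In this comparison 4 of 34 list means passed, against 31 after cisplatin and 28 in the combination against vehicle. The adjustment pools the 3 comparisons, so an adjusted p of 0.0463 here rests mostly on the passes against vehicle.

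None of the 30 tubular injury genes passed between these groups, by limma over all genes or adjusted over the list alone (camera adjusted p = 0.441). The mean of the injury list differed by 0.03 on the log2 scale (SE 0.11, 95% interval -0.22 to 0.28; exact two-sided permutation test p = 0.886), where cisplatin had raised it by 4.20. None of the 35 p53 targets passed either (camera adjusted p = 0.308). Of 27 inflammatory genes Saa1 (-1.21) and Saa2 (-1.08, a call lost without 10 of the 12 libraries in turn), acute phase genes that are close paralogs of each other, fell, the chemokine gene Cxcl2 rose by 0.42, and 24 did not pass (camera adjusted p = 0.327); the counts adjusted over the list alone were the same. Other injury, stress and mitochondrial genes fixed in advance gave log2 differences of 0.09 for Hmox1, -0.32 for Nqo1 (adjusted p = 0.0678), -0.10 for Gpx4, 0.05 for Lonp1 and -0.03 for Sod2, none of which passed.

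Of 50 proximal tubule genes 12 fell and 1 rose, or 14 and 1 adjusted over the list alone. The list median was near the other genes at -0.045, with quartiles of -0.363 and 0.218 (camera adjusted p = 0.00113, and 0.882 with an estimated correlation). Napsa (-1.86, SE 0.13, adjusted p = 6.79e-06), the lactate and short-chain fatty acid transporter gene Slc5a8 (-1.71), the organic anion transporter gene Slc22a7 (-2.06) and Slc22a2 (-0.65, a call lost without 10 of the 12 libraries in turn) fell. Slc34a1 (0.44, adjusted p = 0.464), Slc22a6 (0.10) and Lrp2 (-0.14) did not pass. Of 31 peroxisome genes 6 fell, or 7 adjusted over the list alone, and none rose (median -0.14, camera adjusted p = 3.87e-07; adjusted p = 0.458 with an estimated correlation). Crot (-0.64), Acox2 (-0.54) and Pxmp4 (-0.21) were among them. Of 31 amino acid breakdown genes 4 fell, including Hpd (-0.91), Ivd (-0.56) and Hibch (-0.40). For this list 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.54e-06; adjusted p = 0.882 with an estimated correlation). Acsm3 (-2.19) and Acadm (-0.42) were the 2 of 27 fatty acid oxidation genes that fell, against 5 adjusted over the list alone (camera adjusted p = 0.000344; adjusted p = 0.882 with an estimated correlation). The mean of this list was lower by 0.156 (exact two-sided permutation test, adjusted p = 0.0463), and did not pass with median-of-ratios scaling (adjusted p = 0.125) or z-scores (adjusted p = 0.403). In the list that restrains ferroptosis, Gclc, an enzyme of glutathione synthesis (-0.72), and the fatty acid desaturase gene Scd1 (-1.50) fell and the amino acid transporter subunit gene Slc3a2 rose by 0.22, a call lost without 11 of the 12 libraries in turn. The list had the same counts adjusted over the list alone (camera adjusted p = 0.325). Its mean was lower by 0.105 (exact two-sided permutation test, adjusted p = 0.0463), and did not pass with median-of-ratios scaling (adjusted p = 0.0869) or z-scores (adjusted p = 0.664).

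In the loop and distal tubule Slc12a1 (-2.40, SE 0.32, adjusted p = 0.000906), Umod (-1.40), Ppp1r1b (-1.50) and Cldn19 (-0.84) fell. The other 20 of 24 genes did not pass, among them Slc12a3, the transporter of the distal convoluted tubule (0.41, adjusted p = 0.511). Adjusted over the list alone, 5 fell and 1 rose. The list had a median of 0.11, a mean of -0.23 and a downward camera direction (adjusted p = 0.441). Of 22 collecting duct genes 4 rose: Foxi1, a transcription factor of intercalated cells (0.44), the sodium channel subunit genes Scnn1b (0.36) and Scnn1g (0.25) and the potassium channel subunit gene Kcne1 (0.34). The water channel gene Aqp4, at only 0.25 to 0.47 FPKM in combination libraries, fell by 1.01, a call lost without 7 of the 12 libraries in turn. The other 17 genes did not pass (list median 0.27, camera adjusted p = 3.87e-07, or 0.289 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell, and the list mean was higher by 0.192 in the combination group (exact two-sided permutation test p = 0.0286, the smallest possible; adjusted p = 0.0463). With per-gene z-scores the same test gave an adjusted p of 0.0572. That is the value of the smallest exact p in that setting, where no list mean passed in any comparison.

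Marker lists of tubule segments were drawn up after these values were seen and include the genes that prompted them, so they describe the falls and do not test them. Of 19 markers of the last straight segment of the proximal tubule 14 fell (median -1.07), and their mean was 4.00 ± 0.14 against 5.34 ± 0.36 on the log2 scale. In vehicle their mean was 6.19 ± 0.29, from 5.912 in library 1 to 6.565 in library 3. Between cisplatin and vehicle 11 of them fell and 5 rose. In the combination against cisplatin, 7 of 15 thick ascending limb markers fell (median -0.72, difference of the means -0.81). Among 14 markers of the earlier proximal segments 1 rose and 1 fell (difference 0.16), and none of 10 distal convoluted tubule markers passed with limma (difference 0.18). These lists share 11, 9, 12 and 7 genes with the lists fixed in advance.

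The number of changed genes was 172 without cisplatin library 4, 158 without combination library 2, 152 without combination library 3, 417 with array weights, 176 when only these groups were fitted, and 444 with DESeq2 on the estimated counts of 10 libraries. Of the named genes, 24 of the 43 that passed kept their call under every alternative that tested them, a minimum fold change apart; Igfbp4, Slc3a2, Tecr, Saa2, Slc22a2, Mdk, Spink8, Rtl8b, Aqp4, Pxmp4, Scnn1b, Gclc, Acadm, Cxcl2, Acox2, Pgam2, Hpd, Scd1 and Serpina10 lost it at least once. The camera calls, 5 of 30 lists, did not stand apart from other divisions of the libraries. Of 35 ways of dividing these 8 libraries, 33 gave at least 5 lists, and none of the 5 held with an estimated correlation, where the unadjusted p was under 0.05 for 2 lists.

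**Figure D2:**
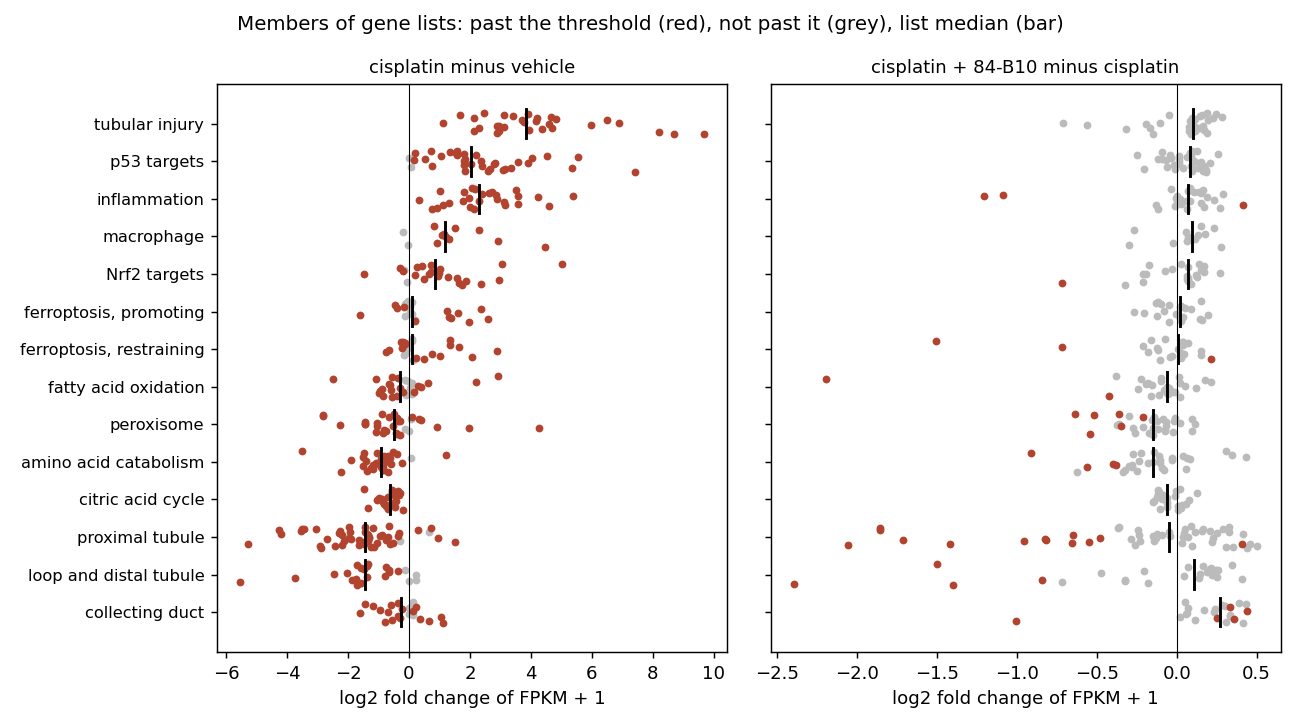
Log2 fold change of FPKM + 1 for each measured member of 14 gene lists, between cisplatin and vehicle on the left and between the combination and cisplatin groups on the right, with members that passed the threshold in red, the others in grey, and the list median as a bar. The horizontal scales differ: the tubular injury list has a median of 3.86 on the left and 0.10 on the right.

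Genes that cisplatin had changed were seldom moved back. Of the 9710 cisplatin-changed genes, 9478 (97.6%) did not pass between the combination and cisplatin groups, 100 (1.03%) changed in the opposite direction, and 132 changed further in the direction of cisplatin. Moved back here means a change opposite to that of cisplatin, and some such genes passed beyond the vehicle level. Cyp7b1, for example, had a mean of 16.8 FPKM in vehicle, 32.2 after cisplatin and 3.65 in the combination group. Of the genes moved back, 85 had risen with cisplatin and were lower with 84-B10. These included Saa1, Akr1c18, Lrg1, a leucine-rich acute phase glycoprotein (-1.17), Arg2, the mitochondrial arginase (-1.08), the protease inhibitor gene Serpina10 (-0.80) and Cp, which encodes ceruloplasmin (-0.52). The other 15 had fallen with cisplatin and were higher with 84-B10, including Pgam2, Mdk, the amino acid transporter gene Slc7a8 (0.41), Alpl, an alkaline phosphatase (0.38), Igfbp4 (0.22) and Tecr (0.21); the calls of Igfbp4 and Tecr were lost without each of the 12 libraries in turn. Array weights gave 120 and 33 genes moved back down and up, and DESeq2 110 and 65. Rescaling to TPM gave 90 and 10, and quantile normalization 77 and 30. Among the 132, 102 were lower in both comparisons, such as Acsm3, Slc12a1 and Umod, and 30 were higher in both. With median-of-ratios scaling 109 were lower and 11 higher in both.

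Both comparisons use the same cisplatin libraries. Simulating all 3 groups without any difference gave 0.01 genes of opposite direction on average over 100 draws (at most 1). That simulation holds no cisplatin effect, so it gives no baseline for the genes moved back. Independent lists of these lengths would share 136.2 genes in opposite and 78.6 in the same direction. With median-of-ratios scaling 92 genes were opposite and 120 the same, against 91.7 and 91.5 for independent lists. When the 4 cisplatin libraries were divided between the comparisons, in 6 ways, 45 to 126 genes were opposite and 30 to 234 the same. Across genes, which are not independent replicates, the fold changes had a covariance of 0.0189 against -0.00561 simulated for shared libraries alone, a difference of 0.0245 (Pearson r = 0.116, Spearman rho = 0.179; simulated r = -0.5).

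**Figure D3:**
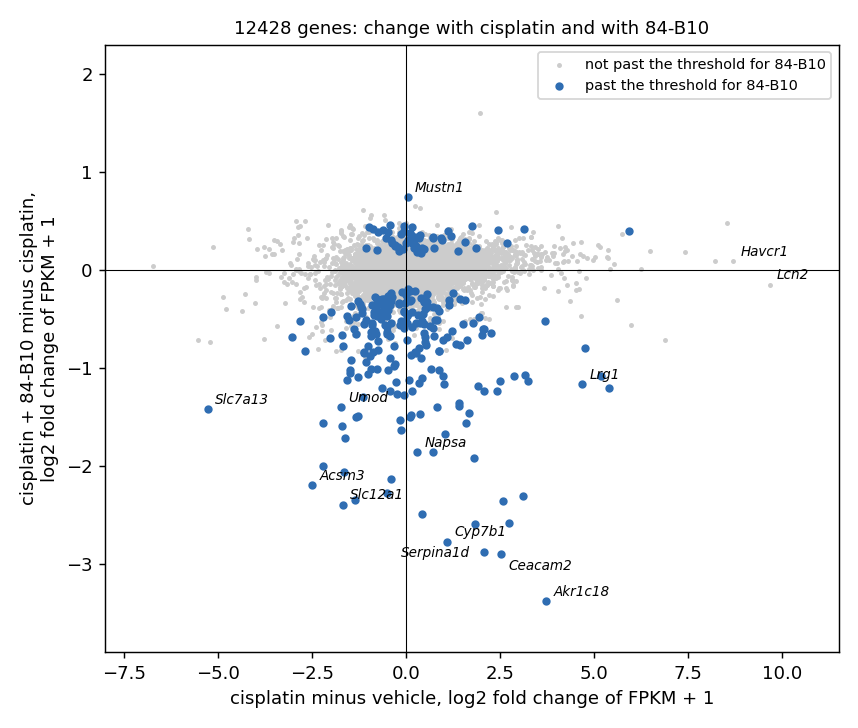
Log2 fold change of FPKM + 1 for 12428 genes, cisplatin minus vehicle on the horizontal axis and combination minus cisplatin on the vertical axis; the 275 genes that passed the threshold in the latter are blue. The 100 blue genes in the upper left and lower right, such as Akr1c18, that also passed for cisplatin moved against their cisplatin change. Some of them passed beyond the vehicle level. The 132 in the lower left and upper right, such as Slc12a1 and Acsm3, moved further away.

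Kidneys of the combination group therefore still differed from vehicle kidneys as widely as those given cisplatin alone. Havcr1 stood at 667 ± 107 against 0.533 ± 0.407 FPKM, Krt20 at 380.4 ± 46.2 against 0.210 ± 0.181 FPKM and Cd68 at 77.4 ± 7.67 against 1.96 ± 0.355 FPKM. Slc7a13 stood at 2.75 ± 0.567 against 386 ± 23.9 FPKM and Umod at 91.6 ± 29.1 against 779 ± 23.4 FPKM (n = 4 per group). All 30 tubular injury genes rose (median 3.96, camera adjusted p = 2.45e-10; adjusted p = 0.139 with an estimated correlation). Of the proximal tubule genes 47 of 50 fell and 3 rose (median -1.60, camera adjusted p = 9.61e-20; adjusted p = 0.218 with an estimated correlation), with the same counts adjusted over the list alone.

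In this comparison 9847 genes changed, 7037 upward and 2810 downward, or 4670 and 4645 with median-of-ratios scaling and 5538 and 5241 by edgeR on the estimated counts. The largest rises under the naming rule were those of Lcn2 (9.52, SE 0.29), Sprr1a (9.003), Havcr1 (8.79), Krt20 (8.30), Cdkn1a (7.60) and the calcium-binding protein gene S100a6 (6.68). The largest falls were those of Slc7a13 (-6.70, SE 0.32), Inmt (-6.70), Egf (-6.26), Nat8f6 (-5.94), Ugt2b37 (-5.18) and Slc22a28 (-5.15), the latter 3 again from families of close paralogs. Kap (-3.50), Slc5a8 (-3.35), Cyp4b1 (-3.002), Slc34a1 (-2.44), Acadm (-1.27), Sod2 (-0.82) and Lonp1 (-0.15, adjusted p = 0.00541) fell. Mdm2 (2.70), Hmox1 (2.45), Ccl2 (2.21), Acsl4 (1.93) and Col1a1 (1.52) rose, and Gpx4 did not pass (0.03, adjusted p = 0.737; -0.27 with median-of-ratios scaling). Camera called 22 of 30 lists; 1 other division of the libraries also gave 22, and none held with an estimated correlation, where the unadjusted p was under 0.05 for 8 lists.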

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

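The tests in this part that weigh explanations were all chosen after the results were seen, apart from the counts over other divisions of the libraries, which were planned, and the test of the most counted genes, whose outcome had not been seen. In groups of 4, a library was singled out when its gap to the nearest other library, divided by the range of the group, exceeded Dixon's limit; 444 groups were examined, 25 were singled out, and chance gives about 22.2. Cisplatin library 1 and combination library 1 each account for 7 of the 25.

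Cisplatin library 1 stood nearer to vehicle than the other cisplatin libraries: it lay at 86.3% of the distance from vehicle to cisplatin, the others at 102.2 to 105.4% (gap over range 0.832). It had the highest Slc34a1 (0.928) and the lowest Fgg (0.874), Srxn1 (0.871), Saa2 (0.838), cell death list mean (0.933) and stress response list mean (0.882) of its group. Combination library 1 had the lowest interferon list mean (0.844), Cdkn1a (0.865), Cp (0.857) and Pgam2 (0.884) and the highest Slc12a3 (0.838), mitochondrial quality control list mean (0.873) and ferroptosis-restraining list mean (0.864). Combination library 2 had the lowest Mdm2 (0.873) and cisplatin handling list mean (0.85). Cisplatin library 2 had the lowest Hibch (0.842), and cisplatin library 3 the highest Pgam2 (0.899) and the lowest ferroptosis-promoting list mean (0.891). Among vehicle libraries, library 2 had the highest Cxcl2 (1, with 0 FPKM listed in the other 3) and the lowest Mdk (0.847), library 3 the highest Slc22a7 (0.894), and library 4 the highest Idh2 (0.862), Krt20 (0.909) and blood list mean (0.842). None of these single libraries was given an explanation.

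The lower level of markers, listed after it was seen, of the last proximal segment and the thick ascending limb with 84-B10 may reflect the compound, the tissue sampled or deeper injury. Library scaling is argued against, since it would move all genes alike, and the lower quartile of all tested genes lay at -0.06 against a median of -1.07 for the proximal segment markers. Cisplatin had raised 85 of the 221 lowered genes, where independent lists of these lengths would share 124.5. Deeper injury that moved each gene further in its cisplatin direction would not lower those 85. A gene raised by cisplatin can also fall when cells that express it are lost, so deeper injury is not excluded for them. It also stays open for the genes that cisplatin lowered, as does less outer medulla in the tissue pieces. The compound itself would give the same list differences of -0.81 in the thick ascending limb and -1.34 in the proximal segment. Markers did not fall alike, with 9 of 15 thick ascending limb and 13 of 19 proximal segment markers off their weighted means by their 95% intervals, but markers shared with other segments would fall less, so a loss of tissue is not excluded.

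After cisplatin 72.1% of changed genes were higher. A few abundant measured genes taking a large share of the counts are argued against as the whole cause. With the FPKM of 10 libraries rescaled to count totals without the 19 genes that were among the 10 most counted of any library, 68.7% were higher, against 71% before. The 13 genes of the mitochondrial genome were not among the measured genes, so a shift in their share was not examined. Median-of-ratios scaling centres the fold changes near 0, so its even split decides nothing. A general rise in RNA per cell stays open, as does a shift spread over many genes: the scaling shift of 0.29 on the log2 scale is relative, and no spike-in was used here.

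The tubular injury list was not lower in the combination group. A mix-up of libraries or too few libraries might account for that, as might 84-B10 pretreatment of the cisplatin group. The labels differ on that pretreatment, and it cannot be settled here because no transcript is known to mark the compound. An exchange of single libraries is argued against, since 0 of the 8 cisplatin-treated libraries lay closer to the mean of the other group than to the mean of their own. Too few libraries is argued against for a fall of the list mean beyond -0.22 on the log2 scale, where the 95% interval ends. On that scale the end lies at -5.2% of the cisplatin rise, and it does not hold for single genes of the list. An exchange of the labels of both whole groups cannot be told apart from the labels as given, because none of the 275 genes that differ is known here to mark the compound. That 84-B10 left these transcripts as they were at 72 h remains a hypothesis, and other readouts of injury were not analysed here.

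Other divisions of the libraries into groups of 4 bear on the counts. The real division was the only 1 of 35 to give as many changed genes in each comparison (9710, 275 and 9847, with at most 0, 101 and 0 in the others). This is the smallest share that 35 divisions allow, so chance is argued against but not excluded. The lists called after cisplatin (23) were also the most of 35 divisions, but the others gave up to 21, with a median of 13.5. None of these lists held with an estimated correlation, so chance stays open for the camera calls. Divisions with unequal numbers of cisplatin libraries on their sides still carry part of the cisplatin difference, so their list counts do not measure chance alone. For the rise of the injury, inflammation and p53 genes themselves, chance is argued against. All 30 injury genes, all 27 inflammatory genes and 33 of 35 p53 targets rose singly. The injury list mean rose by 4.2 on the log2 scale (SE 0.11). Chance also stays open for the lists called between the combination and cisplatin groups (5, with up to 20 in the others, 33 of 35). It stays open as well for the camera calls between the combination and vehicle (22, with 22 in another, 2 of 35). There too, all 30 injury genes, all 27 inflammatory genes and 32 of 35 p53 targets rose singly, which argues against chance for these genes. For genes moved back, 2 of 70 arrangements gave at least 100, the other being the exchange of the whole cisplatin and combination groups (189). Apart from that exchange the highest was 80.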

How the results depend on the processing

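The fits on estimated counts and on the FPKM of the same 10 libraries were chosen after the data were seen. All 61 passing named genes kept their direction and call after cisplatin under every alternative that tested them, apart from a minimum fold change, which named genes were not held to; 35 of 36 did so in the combination against vehicle (Lonp1 lost its call with TPM), and 24 of 43 in the combination against cisplatin. The filter at a mean FPKM of at least 5 tested 64 of 70, 66 of 71 and 35 of 37 named genes, those that passed and those that did not, in the comparisons as ordered in the report. Over 178 gene results and 4258 alternative values, 165 lost and 37 gained a call; 13 values reversed, none of a gene that had passed. Another 52 values changed sign without passing in either setting, 36 of them by less than 1 SE and 16 by more. Changed genes in the combination against cisplatin numbered 417 with array weights, 176 with only these groups fitted and 444 with DESeq2, and genes moved back 153 with array weights and 175 with DESeq2; the cause was not tested. A minimum log2 fold change of 1 left 2096, 69 and 2302 genes in the comparisons as ordered in the report and 25 moved back, by construction. With an estimated correlation 0, 0 and 0 lists were called by camera (unadjusted p under 0.05 for 8, 2 and 8), and the preset value decides these calls. With z-scores 0 list means passed, since only 51 of 102 reached the smallest exact p. With median-of-ratios scaling the log2 fold changes of Casp6 (-0.15), Vdac3 (-0.25) and Xpc (-0.27) after cisplatin and Gpx4 (-0.27) against vehicle in the combination reversed; with quantile normalization Casp6 (-0.14), Xpc (-0.29) and Fth1 (0.86, combination against cisplatin); with edgeR Vdac3 (-0.16), Xpc (-0.28) and Gpx4 (-0.25); with DESeq2 Vdac3 (-0.18), Xpc (-0.29) and Gpx4 (-0.26). Median-of-ratios scaling shifts all genes of a group alike by construction; for the other settings the cause was not tested. Leaving out each library gave 9302 to 9702, 152 to 291 and 9475 to 9901 changed genes, 70 to 100 moved back, and 23 to 24, 4 to 12 and 22 to 24 lists. The lowest gene counts in the combination against cisplatin came without combination library 3 (152), combination library 2 (158) or cisplatin library 4 (172), and its list counts were 12 without cisplatin library 2 and 8 without combination library 1. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered cisplatin and combination libraries correlated at 0.56, 0.25, 0.37 and -0.24 for numbers 1 to 4. Those of vehicle with either other group correlated from -0.08 to 0.08, and 6 of 12 libraries correlated best with their own number. With the replicate number as a block 9696, 316 and 9826 genes changed (244 of the 275 shared), 123 moved back, and 24, 5 and 23 lists were called. Depth limits the genes of low level, and genes with an FPKM of at least 1 in fewer than 4 libraries were not tested.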

Other observations

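The tests on gene lists in this part were planned, and the genes named were chosen after their values were seen. Several gene groups not described above moved with cisplatin. Of 26 interferon-response genes 24 rose, with a median log2 fold change of 1.46 (camera adjusted p = 0.000319; adjusted p = 0.454 with an estimated correlation), including Irf7 (2.59), Isg15 (2.54) and the peptide transporter gene Tap1 (2.44). Of 21 cell cycle genes 20 rose, with a median of 0.68 (camera adjusted p = 0.00173; adjusted p = 0.251 with an estimated correlation), led by the ribonucleotide reductase gene Rrm2 (1.95) and the replication licensing gene Cdt1 (1.502). With quantile normalization 10 rose and 1 fell. Of 13 complement and acute phase genes 12 rose (median 1.12, camera adjusted p = 0.0165; adjusted p = 0.317 with an estimated correlation), with C3 at 5.61 and Serpina3n at 4.64. Cholesterol synthesis genes fell in 14 and rose in 5 of 21 cases (median -0.42, camera adjusted p = 8.37e-05; adjusted p = 0.134 with an estimated correlation), Cyp51 (-2.21) and Idi1 (-1.66) among those that fell. None of these lists passed camera between the combination and cisplatin groups (adjusted p = 0.566, 0.327, 0.211 and 0.162, in the order given), where Cyp51 (-0.47) fell and Cdt1 (0.18) did not pass.

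Clock genes moved in opposite directions after cisplatin. Of 18 listed, 7 rose and 9 fell (camera adjusted p = 0.0137; adjusted p = 0.222 with an estimated correlation, and 0.114 with median-of-ratios scaling at the preset correlation). The clock activators Arntl (2.31) and Npas2 (1.24) and the repressor Nfil3 (2.52) rose, whereas Dbp (-3.97), Ciart (-2.10), Hlf (-1.74), Per3 (-1.33) and Nr1d2 (-1.12) fell. None of the 18 passed between the combination and cisplatin groups, by limma over all genes or adjusted over the list alone (camera adjusted p = 0.468). The hour of tissue collection is not given in the sources used here, and no explanation was tested.

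Transcripts of red blood cells were lower after cisplatin: all 7 measured fell, including Hbb-bs (-2.07), Slc4a1 (-1.61), which the collecting duct also expresses, and Alas2 (-0.75), and none of the 7 passed between the combination and cisplatin groups. Podocyte markers fell in 9 and rose in 1 of 16 cases after cisplatin (median -0.37, camera adjusted p = 0.00115; adjusted p = 0.366 with an estimated correlation), while endothelial markers rose in 6 and fell in 4 of 20 cases, or 5 and 4 adjusted over the list alone, with a median of 0.08 and a downward camera direction (adjusted p = 0.203); with median-of-ratios scaling 3 rose and 9 fell (median -0.16). Nuclear genes of oxidative phosphorylation fell in 43 and rose in 2 of 77 cases (median -0.23, camera adjusted p = 1.07e-11; adjusted p = 0.362 with an estimated correlation), or 40 and 2 adjusted over the list alone and 72 and 0 with median-of-ratios scaling (median -0.52), and none passed between the combination and cisplatin groups (camera adjusted p = 0.939).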
